A study of Morus alba with 4 samples.

How the data were processed

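Leaf RNA of Indian mulberry (Morus alba, genotype Dudia white) was sequenced from 2 well-watered and 2 drought-stressed samples, which the series describes as biological replicates. The groups were taken from the treatment label of each sample. The replicate numbers 1 and 2 used here follow the order of deposition, name a library and pair nothing.

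Per the submitters' processing notes, the authors used bcl2fastq 2.20, HISAT2 (a spliced aligner) and featureCounts (a read counter). The settings, the genome build, the annotation and the normalization tool are not given in the sources used here. Each deposited file holds 1 whole-number score for each of 37553 rows, and per the file headers this score is a normalized value. The spacing of the scores shows how they were made. In well-watered library 1 every one of the 18405 values from 1 to 150 fell on the rounded multiples of 1.22, which cover 82.0% of whole numbers, and in drought library 1 every value fell on those of 1.11. In the other 2 libraries the step was below 1, and whole numbers that 2 multiples of the step round to held 1.85 and 2.10 times as many rows as the others. The scores are therefore whole read counts multiplied by 1 factor per library and rounded. A read was worth 1.22 and 0.86 in well-watered libraries 1 and 2 and 1.11 and 0.84 in drought libraries 1 and 2, so a value of 10 stood for 8.18 to 11.9 reads. The step search was checked on simulated data with known steps. Because rounding with a step below 1 merges neighbouring read counts, the reads were not recovered exactly and no count model was fitted.

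The rows are transcripts, not genes, and fall into 5 classes by the form of their identifier. There were 27648 rows with a RefSeq predicted-mRNA accession, 2245 with a RefSeq predicted non-coding RNA accession, 6251 transcripts from 5130 loci with the identifiers a transcript assembler assigns (MSTRG, called assembled rows below), 392 tRNA rows and 1017 rows named by a gene identifier. The files pair no identifier with a gene name or product, and no reference was used here. None of the 28 gene lists that had been fixed on product descriptions before the data were examined could therefore be matched to a row, and no pathway, transcription factor family or marker of another cell type was tested. The tRNA identifiers give the amino acid and anticodon, and these are the named genes that could be described. No transcript has coordinates in the files.

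Before the data were examined a count model had been planned, with a moderated test on the log scale in its place if the files held normalized values. The latter was used: limma 3.58.1 (R 4.3.3) with a trend of the spread with level was fitted to log2(value + 1) of all 4 libraries in 1 fit, with no covariate. Rows with a value of at least 10 in at least 2 libraries were tested, 28254 in all. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, and an adjusted p under 0.05 was the threshold. Fold changes are drought minus well watered on the log2(value + 1) scale, which understates the change of rows with low values. The fit had 2 residual and 5.96 prior degrees of freedom. On simulated data for this comparison (28062 rows with the real means and read worths, 200 of them changed), all 100 rows changed 4-fold and 86 of 100 rows changed 2-fold passed, with 0 false calls. The simulation used 1 spread setting for all rows and both groups. Only rows with means of at least 50 were changed, and rows with means of 100000 or more were left out. It had no rows that share reads and no shift of abundant rows, so the real error rate is less well known.

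The planned rule for named rows was applied with the column total of the deposited values as the base for the 5 CPM of the rule. It took rows past the threshold with a mean of at least 5 CPM and no overlap between the groups, 29 rows in all. Of these, the 2 with the largest rise and the 2 with the largest fall are given by identifier. Because a read was counted in many rows, 5 CPM of the column total is a high level here. MSTRG.2521.1, with group means of 31649 and 10983.5, had 5.67 CPM, while the median tested value was 127 to 131 in the 4 libraries. The planned rule also names the 3 rows with the highest sums. The tRNA rows and the row classes were chosen for description after the identifiers had been seen, and were compared as sets with camera in limma, with a preset correlation of 0.01 and with an estimated one, and with fry. Of the amino acids only threonine was taken as a set.

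A row's reads can be counted in other rows. Of the tested rows, 10162 had the same 4 values as at least 1 other row, and 22267 distinct sets of values remained. The alternatives tried were other scalings, filters, pseudocounts, spread estimates, row sets, a minimum fold and leaving out each library. The sources used here do not state whether strand was used in counting, so reads of overlapping rows on opposite strands cannot be told apart. Replicates of a group differed by more than sampling noise: over 9002 rows with means of 200 to under 1000, the chi-square per row of the implied reads was 4.40 in the well-watered and 10.1 in the drought pair. Intervals of counting error were not attached to single values, since reads are not independent molecules here.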

Results

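Mulberry plants were grown in pots of about 30 kg and kept for 14 days at 100% (well watered) or 40% (drought) of the soil's field capacity, the water the soil holds after draining. Mature leaf tissue of 2 samples per treatment was sequenced, and the comparison asks which leaf transcripts differ in level under the lower water supply. The deposited values summed to 3729609294 and 3723910998 in well-watered libraries 1 and 2 and to 4773539793 and 2910603473 in drought libraries 1 and 2. These sums exceed any number of reads because a read was counted in many rows. The predicted-mRNA rows alone summed to 13865854, 13404918, 15683648 and 11174504, which stood for about 11346853, 15587114, 14129413 and 13302981 reads summed over rows at the worth of a read in each library. Of 20946 tested predicted-mRNA rows 16946 had distinct sets of values, so a read can be counted more than once in these sums too. In the order of the libraries just given, 31332, 32112, 31515 and 32164 of the 37553 rows had a value above 0, and 3896 rows were listed at 0 in all 4.

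Assembled transcripts took 99.3% to 99.5% of the summed values in every library. The 65 rows of 2 assembled loci, MSTRG.1 and MSTRG.2, held 69.0% and 69.6% of the sum in the well-watered libraries and 70.2% and 71.6% in the drought libraries. What these loci encode is not given in the files. The 3 rows with the highest sums did not pass the threshold. MSTRG.1.8 had values of 49647477 and 49271422 in the well-watered libraries and 65129898 and 41472203 in the drought libraries, a log2 fold change of 0.07 with a standard error of 0.73 (adjusted p = 0.969). MSTRG.1.6 had 46911839 and 47150876 in the well-watered and 62119997 and 40251607 in the drought libraries, and MSTRG.2.2 had 46597096 and 46801188 against 61679666 and 40081915. The spread of these rows lay between the 2 drought libraries: the 153 tested rows with means of 1000000 or more were 1.65 times as high in drought library 1 as in drought library 2 (median), while the well-watered pair differed by a median of 0.0048 on the log2 scale. Rows with means of 200 to under 1000 differed by a median of -0.02 between the drought libraries.

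**Figure D1:**
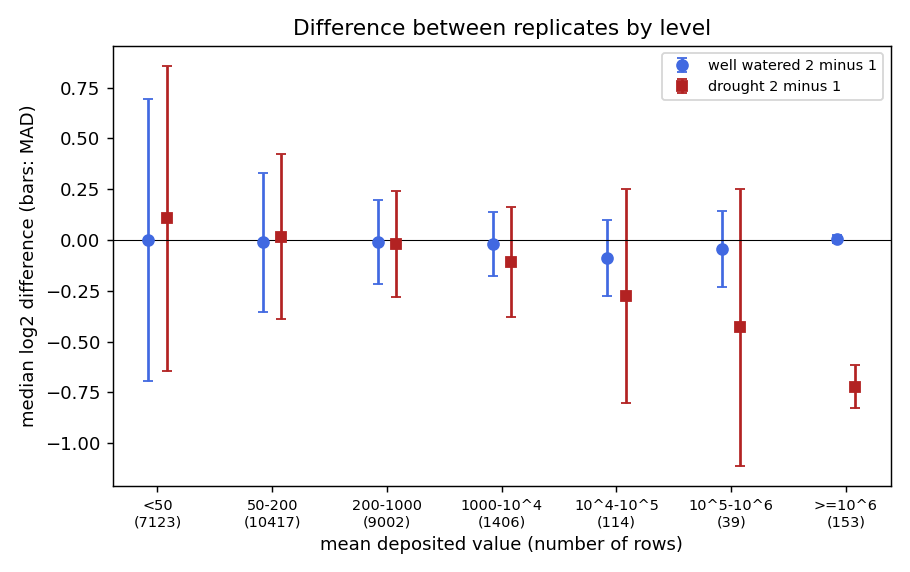
Median log2 difference between the 2 libraries of each treatment (y axis) for tested rows grouped by their mean deposited value (x axis, number of rows in brackets). Bars are the median absolute deviation over rows. Blue points (well watered) stay near 0 at every level, while red points (drought) fall to -0.72 for the 153 rows with means of 1000000 or more.

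Libraries of the same treatment were closer to each other than to those of the other treatment. Over the 28254 tested rows, Pearson's correlation of log2 values across rows was 0.978 within the well-watered pair and 0.974 within the drought pair. Across treatments it lay between 0.933 and 0.945. The median absolute log2 difference per row was 0.21 and 0.27 within the pairs and between 0.33 and 0.38 across treatments. Rows are not independent replicates, so these values describe the libraries and carry no test.

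Drought changed 2771 of the 28254 tested rows: 1304 were higher and 1467 lower at an adjusted p under 0.05 (limma). Changes of at least 2-fold made up 698 of the higher and 996 of the lower rows, and changes of at least 4-fold 240 and 330. An unadjusted p under 0.05 was reached by 6896 rows, against 1412.7 expected by chance. In all 2771 called rows both drought libraries lay on the same side of both well-watered libraries. With 2 libraries per group, a row with overlapping groups cannot reach the threshold in this fit, so this follows from the calls. Among all tested rows 53.1% were so separated, where chance gives 33.3%. This share and the 1412.7 are expectations for each row taken alone. Rows are not independent, so a difference between libraries of any cause can exceed them, and neither is a test. With rows of identical values counted once, 913 were higher and 1143 lower. Few calls remained when 1 library was left out, in fits with 1 residual degree of freedom: without well-watered library 1, well-watered library 2 or drought library 2 no row passed, although 3400, 4074 and 5768 rows had an unadjusted p under 0.05, and without drought library 1 the test called 10 higher and 38 lower, 26 of them also called in the main fit.

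Predicted mRNAs made up most of the tested and of the changed rows, and more of them fell than rose. Of 20946 tested, 833 were higher and 1041 lower in drought, together 8.95%. That share was below the 9.81% of all tested rows and the 13.4% of assembled transcripts, and above the 5.88% of non-coding RNAs. At least 4-fold changes were found in 184 higher and 220 lower predicted-mRNA rows. Predicted non-coding RNAs changed in 58 of 986 rows, 18 higher and 40 lower. Against a minimum of 1.5-fold the direction turned, with 8 higher and 3 lower, while the other alternatives with all 4 libraries and calls kept more lower rows. Of the main calls, 9 higher and 8 lower were at least 4-fold. The summed values of the non-coding rows were 13152664 and 13336667 in the well-watered libraries, 14103044 in drought library 1 and 4209216 in drought library 2. Of each sum, 85.3% to 91.7% lay in 2 rows with means of 1000000 or more, neither of which passed, so the drop is mostly theirs. The other non-coding rows summed to 1418600, 1457059, 1166494 and 619821 in the same order. Among assembled transcripts, which can be further isoforms of annotated genes or transcripts outside them, 436 were higher and 361 lower of 5955 tested. This balance turned with library totals as the scale (157 and 187), against a minimum of 1.5-fold (86 and 114) and with no trend in the spread (58 and 101). It held in the other alternatives with all 4 libraries that called assembled rows. Of the calls in the main fit, 44 higher and 91 lower were at least 4-fold. Rows named by a gene identifier were higher in 10 and lower in 25 of 336 cases. Many rows of a class hold identical values. Counted once within their class, the calls were 693 higher and 880 lower for predicted mRNAs, 12 and 39 for non-coding RNAs, and 375 and 332 for assembled transcripts. A fit with identical rows kept once over all classes, in which a shared set of values stays in 1 class only, gave 551 and 780, 3 and 27, and 343 and 312. As whole sets, none of these 4 classes passed a test against the other rows, with the preset or with an estimated correlation. Camera's adjusted p was 0.538 for predicted mRNAs, 0.474 for non-coding RNAs, 0.474 for assembled transcripts and 0.474 for gene-identifier rows, and median log2 fold changes lay between -0.06 and 0.04.

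**Figure D2:**
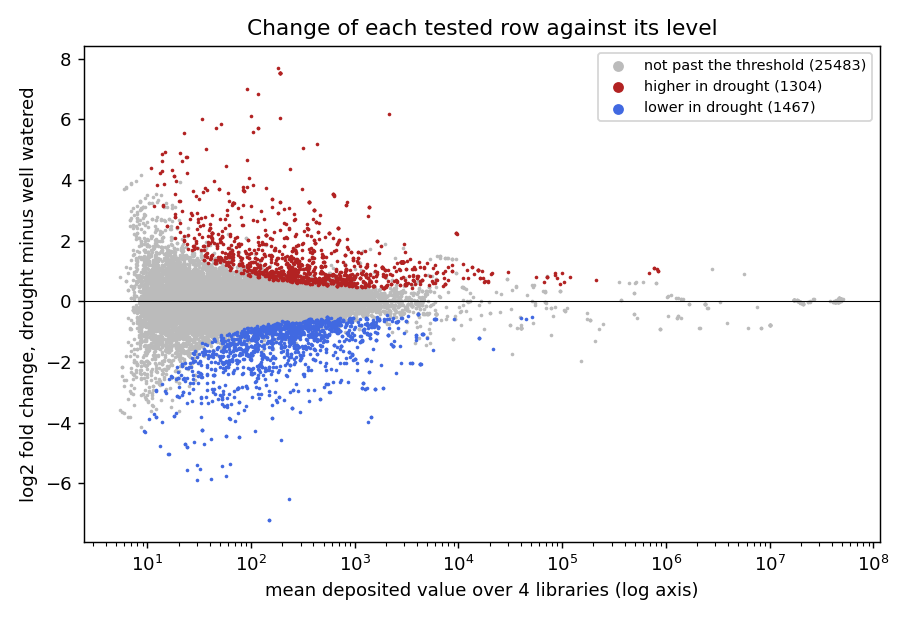
Log2 fold change of each tested row, drought minus well watered (y axis), against its mean deposited value over the 4 libraries (log x axis). Red points are the 1304 rows higher and blue points the 1467 rows lower at an adjusted p under 0.05, and grey points are the other rows. None of the rows with means of 1000000 or more, at the right edge, passed.

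Some rows were near 0 in the libraries of one treatment only. At least 50 in both drought libraries with at most 5 in both well-watered ones was seen in 16 rows (11 distinct sets of values), and the opposite in 12 rows. The largest changes were ranked among called rows with means of at least 100, with identical rows taken once. Among the 5 largest rises so ranked, the row with the highest level was a predicted mRNA with values of 42 and 74 in the well-watered libraries and 3290 and 5225 in the drought libraries, a log2 fold change of 6.19 with a standard error of 0.29 (adjusted p = 5.04e-05). A predicted mRNA at the other end fell from 528 and 388 to 3 and 5, a log2 fold change of -6.53 with a standard error of 0.34 (adjusted p = 7.89e-05). Another fell from 316 and 273 to 1 and 1. These rows were picked after their values were seen, and without gene names their function was not analysed here.

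By the rule fixed beforehand, the rows named are abundant assembled transcripts. Their folds are taken from the log2 fold changes and can differ slightly from the ratio of the printed means. MSTRG.1787.2 rose from a mean of 484285 ± 3427 (SD, n = 2) to 1054569 ± 157307 (SD, n = 2), 2.17-fold, with a log2 fold change of 1.11 and a standard error of 0.21 (adjusted p = 0.0159, limma). MSTRG.1789.2 had almost the same values, 484301 ± 3424 and 1054580 ± 157309 (SD, n = 2), so these 2 rows share nearly all their reads and count as 1 observation. MSTRG.2521.1 fell 2.97-fold, from 31649 ± 4561 to 10983.5 ± 4030 (SD, n = 2), with a log2 fold change of -1.57 and a standard error of 0.23 (adjusted p = 0.00536). MSTRG.14.2 fell 1.49-fold, from 53752 ± 15.6 to 36170.5 ± 5368 (SD, n = 2), with a log2 fold change of -0.58 and a standard error of 0.14 (adjusted p = 0.0381). Of the 29 rows that met the rule, 25 were higher and 4 lower. When the rule's level of 5 CPM was the filter of the test itself, 0 of these 29 passed, with a lowest adjusted p of 0.0749. All 4 named rows lost their call in that fit, against a minimum of 1.5-fold and with no trend in the spread. MSTRG.1787.2 and MSTRG.1789.2 also lost it when rows with means above 1000000 were left out (adjusted p = 0.336) and without any 1 library except drought library 1. MSTRG.2521.1 and MSTRG.14.2 lost it without any 1 of the 4 libraries. MSTRG.14.2 also lost it when library totals set the scale (adjusted p = 0.299), with no filter on low values (0.0787), with a robust spread estimate (0.138), with identical rows counted once (0.0510), with precision weights (0.152) and with rows above 1000000 left out (0.158). The log2 fold changes hardly moved in the alternatives with all 4 libraries: 1.10 to 1.11, -1.58 to -1.57 and -0.59 to -0.58. Filters, row sets, spread estimates, a minimum fold and pseudocounts hardly enter the fold of such rows. Library totals gave the drought libraries factors of 1.28 and 0.78, which nearly cancel in their mean, and the other scalings had factors near 1. These narrow ranges therefore follow from the settings and are no support for the folds.

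Among tRNAs, 7 of 15 tested threonine rows rose in drought. Transfer RNAs carry amino acids to the ribosome, and of 392 tRNA rows 31 had values high enough to test. At the threshold 7 tRNA rows were higher and 0 lower (limma), and all 7 were threonine tRNAs, 5 with the anticodon GGU and 2 with UGU, out of 15 threonine rows tested. TRNAT-UGU-7 had values of 35 and 38 in the well-watered and 117 and 78 in the drought libraries, a log2 fold change of 1.37 with a standard error of 0.30 (adjusted p = 0.0253). TRNAT-GGU-9 went from 163 and 146 to 400 and 285, a log2 fold change of 1.13 with a standard error of 0.21 (adjusted p = 0.0130). The called threonine rows had log2 fold changes of 1.08 to 1.37 and the other 8 of 0.37 to 1.01. Drought library 1 exceeded both well-watered libraries in 15 of 15 threonine rows, and drought library 2 in 12 of 15. Among the other amino acids, the phenylalanine row TRNAF-GAA-12 had a log2 fold change of 0.66 (adjusted p = 0.0550), the glutamine row TRNAQ-UUG-7 of -0.99 (adjusted p = 0.0802), and the pair of tryptophan rows of -2.89 and -2.87 with values of 11 and 13 in drought library 1 and 0 in drought library 2. At an unadjusted p under 0.05 there were 9 higher and 4 lower tRNA rows, and adjusted over the list alone 8 higher and 1 lower. Threonine was the only amino acid taken as a set, and it holds all 7 called tRNA rows. Its set tests use the same values as those calls and are no separate support for them. As a set the 15 threonine rows were higher than other rows by camera with the preset correlation (adjusted p = 2.00e-06), a call lost with an estimated correlation (adjusted p = 0.338). The estimated correlation of these rows was 0.922. Fry, which tests whether the rows move 1 way on balance, gave an adjusted p of 0.181. The set of all 31 tRNA rows likewise passed with the preset correlation (adjusted p = 0.00424) and not with an estimated one (adjusted p = 0.414). The copies of a tRNA are near-identical in sequence, so how their reads were divided is uncertain. The count of threonine rows past the threshold fell from 7 to 0 when library totals set the scale, with no filter on low values, with no trend in the spread, against a minimum of 1.5-fold, and without any 1 of the 4 libraries. The log2 fold changes of these 7 rows stayed at 1.03 to 1.38 in the alternatives with all 4 libraries and at 0.68 to 1.655 without a library. The first range is narrow by construction, since most of those alternatives do not or hardly enter the fold. For TRNAT-GGU-9 the log2 fold change was 1.1247 under library totals and 1.1251 in the main fit, but its standard error rose from 0.21 to 0.46 (adjusted p = 0.234). With no filter its standard error stayed at 0.21 (adjusted p = 0.0521), and with no trend it was 0.23 (adjusted p = 0.0982).

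**Figure D3:**
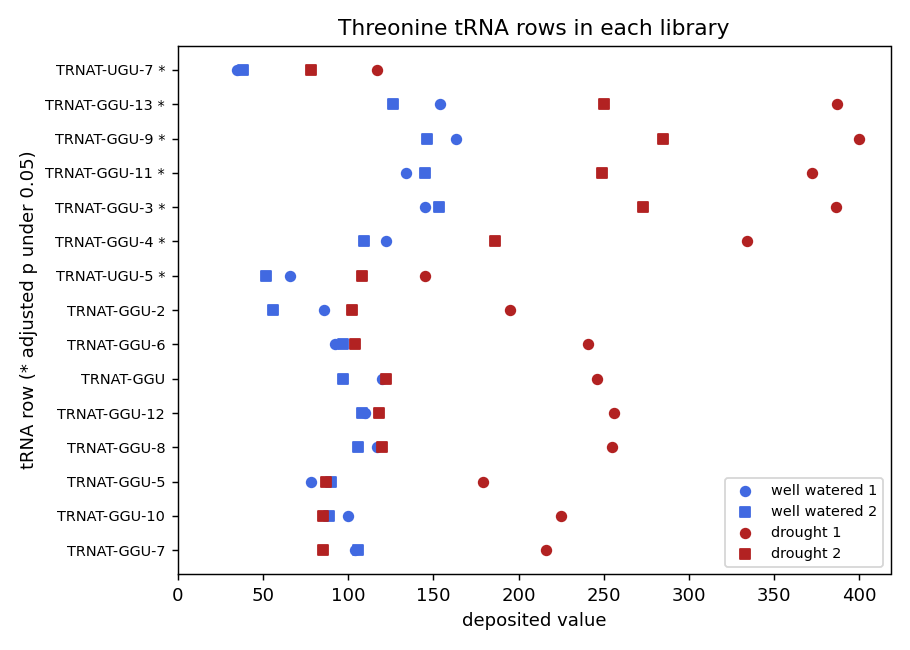
Deposited values (x axis, from 0) of the 15 tested threonine tRNA rows (y axis) in each of the 4 libraries, ordered by log2 fold change, with stars at the 7 rows past the threshold. Blue points are well-watered and red points drought libraries, with circles for library 1 and squares for library 2. Drought library 1 holds the highest value in every row.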

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

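The main result was 1304 higher and 1467 lower rows. Both counts stayed within 1.5 times of these under recomputed median-ratio factors, upper quartile factors, the 10 top rows left out, a robust spread estimate and, chosen after seeing the data, pseudocounts of 0.5 and 5, a mean of at least 50, identical rows counted once, assembled rows left out, precision weights, and rows above a mean of 1000000 left out. Recomputed median-ratio factors were 0.9992 to 1.0014 and upper quartile factors 0.993 to 1.016, so these 2 refits used nearly the same values as the main fit. Library totals, with factors of 1.28 and 0.78 in drought libraries 1 and 2, differed more. The counts moved further under 5 settings, of which the spread without a trend was also chosen after seeing the data. Scaling by library totals gave 475 higher and 623 lower, no filter on low values 709 and 811, a test against 1.5-fold 287 and 372, and no trend in the spread 265 and 419. A mean of at least 5 CPM of the column total left 263 rows, among them the 153 with means of 1000000 or more. It gave 0 higher and 0 lower, with 49 rows at an unadjusted p under 0.05 (limma). This level leaves only very abundant rows, since the median tested value was 127 to 131 in the 4 libraries. Under this last filter the folds of the rows named by identifier, which a filter does not enter, were unchanged and their standard errors larger (0.33 against 0.21 for MSTRG.1787.2). The cause of the changes was not tested. Leaving out 1 library gave 0 to 10 higher and 0 to 38 lower rows: 0 without well-watered library 1, well-watered library 2 or drought library 2, and 10 and 38 without drought library 1. Those fits have 1 residual degree of freedom and assume that the lone library varies like the other group. The share of higher rows among calls (47.1% in the main fit) lay between 38.7% and 47.7% in the settings that used all 4 libraries and made calls. The 4 rows named by identifier kept their call in 40 of 60 comparisons with alternatives that used all 4 libraries. MSTRG.1787.2 and MSTRG.1789.2, which count as 1 observation, each kept it in 11 of 15. The 7 threonine tRNA rows kept their call in 76 of 105. These rows move together (estimated correlation of 0.922 over the 15 tested threonine rows), so the comparisons are not independent. The DESeq2 test, voom with TMM factors and thinning to equal depth were not run, since the values are not counts, and no gene list could be tested for want of product names. No paired analysis was possible because the labels give no replicate numbers. Depth limits rows with low values: the filter at 10 stands for 8.18 to 11.9 reads.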

Other observations

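All tests in this part were chosen after the result was seen, except the count over other splits of the libraries.

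Opposite changes of 2 transcripts of the same assembled locus were found at 1 locus, MSTRG.12999, which is named after its values were seen. MSTRG.12999.1 was lower, with a log2 fold change of -0.54 and a standard error of 0.11 (adjusted p = 0.0196, limma), and MSTRG.12999.3 was higher, with 0.71 and 0.18 (adjusted p = 0.0437). Over all classes, 33 rows with means from 10000 to under 100000 were higher and 7 lower, and of the rows from 100000 to under 1000000, 9 were higher and 0 lower. In the range from 50 to under 200 the balance was the other way, with 322 higher and 542 lower. The 2 drought libraries differed in the abundant ranges, by medians (library 2 minus 1, log2 scale) of -0.27 from 10000 and -0.43 from 100000. Many of the abundant rows share reads, so these are fewer observations than rows. With a mean of at least 5 CPM as the filter, 29 of these called rows were among the 263 tested, and 0 passed.

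Only the treatment split gave rows past the threshold. The 4 libraries can be divided 2 and 2 in 3 ways, and the real split gave 2771 rows past the threshold while the highest of the others gave 0. As many rows were reached by 1 of the 3 splits, the real one. With 3 splits the share cannot fall under 0.05. In the other splits each group mixes both treatments, so a difference between treatments adds to the spread and works against calls. The 0 is therefore no separate support.

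The most abundant rows were lower in drought library 2 than in drought library 1. All 23 loci or single rows with means of 1000000 or more had this direction, by 1.51 to 5.08 times. Rows with means of 200 to under 1000 differed by a median of -0.0212 on the log2 scale, and those of 1000000 or more by -0.72. The difference was graded between these levels. Its median was -0.11 from 1000 to under 10000, -0.27 from 10000 to under 100000 and -0.43 from 100000 to under 1000000. A scaling factor moves all rows alike, so 1 factor cannot remove this gap. The median-ratio factors of the deposited values were 0.9992 and 1.0014 in drought libraries 1 and 2, which holds rows of middle level near 0. Whether the abundant rows or the other rows shifted can therefore not be told from these values. The depth difference is argued against by the well-watered pair, whose gap in the worth of a read was larger (1.22 and 0.86 against 1.11 and 0.84) and whose abundant rows differed by a median of 0.0048. One pool of RNA present in different amounts would give 1 fold. The median fold was 1.72, and 20 of the 23 lay within 1.37 times of it, the largest difference of any of these loci in the well-watered pair. The other 3 lay at 3.60, 3.60 and 5.08. So 1 fold does not describe all 23, and whether most of them are a single pool stays open. Some of the 23 had the same fold to many digits, as MSTRG.10725 and MSTRG.10727 (3.60428 each) and MSTRG.6143 and MSTRG.6144 (1.75683 each). Shared reads give such equal folds, so the 23 are fewer observations than their number. How far the others share reads stays open. No explanation for a difference within a treatment was tested beyond these.

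The threonine tRNA rows may reflect more than 1 source of reads. If 1 set of reads were counted in full at every copy, all copies would hold the same values, but the 13 GGU copies held 13 distinct sets of values, from 85 to 285 in drought library 2. A rise of all tRNA rows is argued against by the 16 tested rows of other amino acids, whose median log2 fold change was 0.068 (median absolute deviation 0.53) against 1.01 for threonine. Partial sharing of reads between copies, reads of longer transcripts that run across these tRNA genes, and a response to drought remain open, and the first pair needs the alignments.

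Even numbers of reads were more common than odd ones among low values. In the 2 libraries whose read counts can be read off the values (well watered 1 and drought 1), rows at 2 reads were 2.2 and 2.24 times as common as the mean of rows at 1 and 3 reads. The excess was seen at 2, 4, 6, 8 and 10 reads in both libraries. Its origin was not tested, and whether the libraries were sequenced in pairs is not given in the sources used here.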
